A study of Mus musculus with 14 samples.

How the data were processed

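Total RNA was extracted with Ambion's miRNA isolation kit and labelled with a Cy3/Cy5 kit of Genisphere after reverse transcription with Superscript II, per the labels' protocols. Each of 14 arrays carried a sample in Cy5 and the pool of 7 ad libitum controls in Cy3. The deposited values are 1 log2 ratio per probe and array in a single table of 21582 probes; that they are log2 ratios is read from the values and the two-channel design, since scale, centring and direction are not stated. The scanner, background correction and normalization are not given in the sources used here. Nothing was centred per probe, and array medians differ, so arrays were not all centred before deposit. No signal column was used, so brightness, and which spots lay above background, is unknown.

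Exact values of 0 and values at the highest value in the table recur on every array and were set to missing as placeholders (555 to 3155 per array). Each array was centred on its median. A probe was tested when it had values on at least 4 arrays of each group, which left 20876 probes and left out 706. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 14 arrays in 1 fit, two-sided, prior degrees of freedom 5.88), with Benjamini-Hochberg adjusted p under 0.05. The contrasts were alcohol-fed minus pair-fed and each group's mean against 0, the last because the reference is the control's RNA and no control was hybridised against it. No 2 arrays shared over 2.97% identical values, so none was a copy of another and each was counted as 1 replicate. This does not show that the arrays are independent. Errors printed are limma standard errors. Each combines 1 moderated variance per probe, taken from both groups, with the number of arrays with a value, 4 to 7 per group. The error of a group is therefore not its own spread, and that of a difference covers both groups. Leaving out an array of 1 group can thus change a call in the other. Probe intervals are 95% intervals.

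Names come from the array's platform annotation, which is old, checked against RefSeq gene names of assembly GRCm38.p6: 16635 probes had 1 symbol, 113 several and 4834 none, 15957 matched by gene number, and 0 symbols needed an update. No coordinates are given, since the files name no genome build. Probes were tested singly. Where a gene had several, it is named by the probe with the smallest p, and the values of its other tested probes are given beside it, as a range where there are more than 2.

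The 32 gene lists, 16 of cell-type markers and 16 of responses, were fixed before the data were examined, as were the tests, most of the other settings tried and the rule for named genes. That rule takes the 12 largest rises and 12 largest falls past the threshold among named probes, or the 10 smallest p where fewer than 10 pass, plus up to 4 members of each list with the smallest p. The number of list members printed, 1 per list for alcohol-fed against pair-fed and for pair-fed against the reference and 2 for alcohol-fed against the reference, was narrowed after the data were seen. For list tests the probes of a gene were averaged (14610 genes) and missing values filled with the group mean (3.37% of values). Camera with an inter-gene correlation of 0.01 was the main test, with an estimated correlation and fry as alternatives, adjusted over the 32 lists. Counts of members per list take single probes over all probes tested, and counts adjusted over the list alone take the gene averages. The latter join both directions, and their split can differ from that of the former.

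The main limma fit and the 3 list tests were tested on simulated data with the real spreads and missing values, with 200 of 20876 probes changed for limma. For alcohol-fed against pair-fed limma recovered 0% of 2-fold, 31.5% of 4-fold and 79.0% of 8-fold changes, calling 0, 5 and 6 unchanged probes. For alcohol-fed and pair-fed against the reference it recovered 69.5% and 67.5% of 4-fold changes, in a table where all other probes had a mean of 0. Ribosomal protein genes were shifted by 0.5 on the log2 scale among 14610 genes. For alcohol-fed against pair-fed this gave an adjusted p of 3.04e-08 with camera, 0.00186 with an estimated correlation and 0.000425 with fry. Simulated noise was independent between probes, whereas the real list had an estimated inter-gene correlation of 0.186. These p-values therefore do not show that a real shift of this size would be called. Against the reference the same list gave 2.87e-08, 0.000587 and 1.47e-05 for alcohol-fed and 5.74e-06, 0.00265 and 8.67e-05 for pair-fed. No other list was called in any of these tests. In the simulation against the reference all other genes had a mean of 0. The real mean ratios had an SD across probes of 1.12 for alcohol-fed and 1.09 for pair-fed. Camera compares a list with other genes, so its values here do not carry over to the real ratios. The other settings were not tested on simulated data.

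Other settings chosen beforehand were values as deposited, quantile and scale normalization, other limits on missing values, eBayes with trend and robust, array weights, the mean of a gene's probes, a 1.5-fold minimum, the replicate number as a block and leaving out each array. Added after seeing the data were placeholders kept as values, values within 0.012 of 0 made missing, and leaving out the arrays with most placeholders or those whose deviations correlate most. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.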

Results

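RNA of C57Bl6 mouse fetuses was measured on 14 two-colour arrays of 21582 probes. In the alcohol-fed group (n = 7) the pregnant mothers were exposed to about 180 to 200 mg/dl ethanol from gestational day 15 to 18, and in the pair-fed group (n = 7) they received maltose dextrin instead, as titles and protocols call it (maltose dextrose in the description and design text). Fetuses were delivered on gestational day 19, and the tissue is not given in the sources used here. Every array carried 1 sample in Cy5 beside the same pool in Cy3, total RNA of 7 animals fed freely (ad libitum), so that this pool is both the common reference and the untreated control. The labels give 4 days of exposure in the protocol and 5 days in the titles. Nothing says that the 7 samples of a group came from separate litters, so p-values measure the spread between these samples, which may be technical.

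The median of the deposited log2 ratios of alcohol-fed arrays 1 to 7 was -0.30, 0.55, 0.57, 0, 0.38, -0.14 and -0.01, and of pair-fed arrays 1 to 7 it was 0.34, 0.63, 0.001, 0, 0.31, 0 and -0.43. Values at exactly 0 or at the highest value in the table, read as placeholders and left out of the tests, made up 2.57% to 14.6% of an array. The medians given above still include them. Without placeholders the medians ran from -0.62 (pair-fed 7) to 0.68 (pair-fed 2). Those of 0 became 0.003 (alcohol-fed 4), 0.05 (pair-fed 4) and -0.17 (pair-fed 6). Arrays correlated with each other at r = 0.257 to 0.692 across probes, which are not independent replicates, and the median correlation was 0.451 both within and between the groups. The number of arrays limits the precision.

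**Figure D1:**
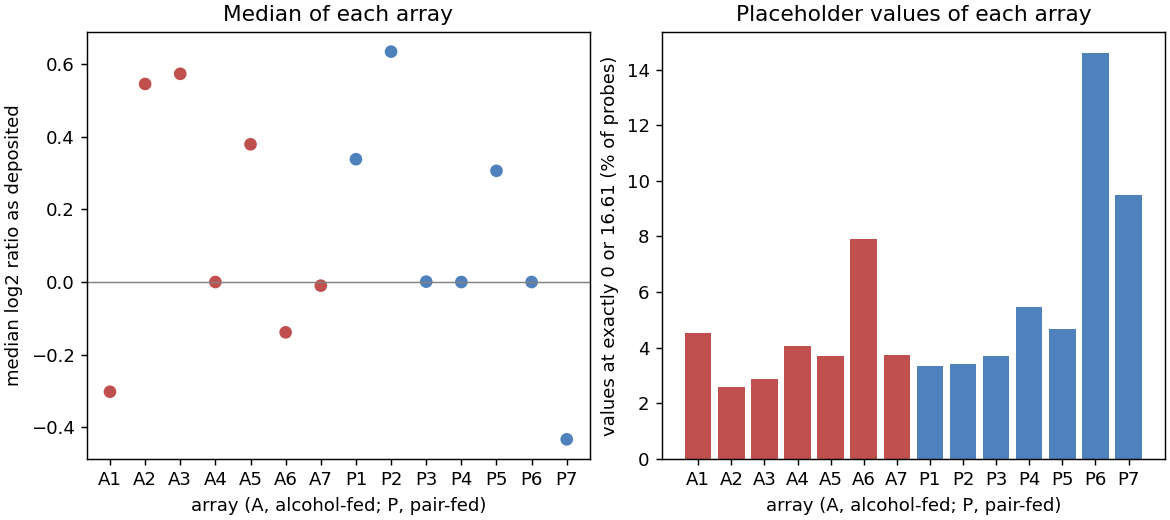
Left, the median deposited log2 ratio of each array (y axis, log2) against the array, A for alcohol-fed and P for pair-fed; right, bars of the share of placeholder values per array (y axis, % of probes). Medians, with placeholder values included, run from -0.43 to 0.63, and pair-fed array 6 has the highest placeholder share, 14.6%.

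The first comparison asked how ethanol exposure differed from the matched sugar diet, with the reference cancelling. No named gene passed the test: limma called 0 of 20876 probes at an adjusted p under 0.05, with 881 at an unadjusted p under 0.05 where chance gives 1043.8, and 0 lists were called by camera or fry. The probe with the smallest p was Ahrr, the repressor of the aryl hydrocarbon receptor, with a log2 difference (alcohol-fed minus pair-fed) of -7.02 ± 1.16 (SE), measured on 4 arrays of each group. Itga4, the integrin alpha 4 chain of leukocyte adhesion, stood at 2.29 ± 0.50 and the cell polarity gene Pard6g at 1.85 ± 0.41, with the gene's other probe at -0.06. The other 7 of the 10 smallest p belonged to 1700063A18Rik (-3.16 ± 0.72), the DNA crosslink repair gene Dclre1a (-2.02 ± 0.47), the solute carrier Slc35g3 (1.92 ± 0.45), the membrane fusion gene Napa (-1.74 ± 0.43), 4930404H11Rik (-1.75 ± 0.43), the cathepsin Cts6 (-2.50 ± 0.62) and the helicase Brip1 (-1.93 ± 0.49). All 10 had a limma adjusted p of 0.9996.

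**Figure D2:**
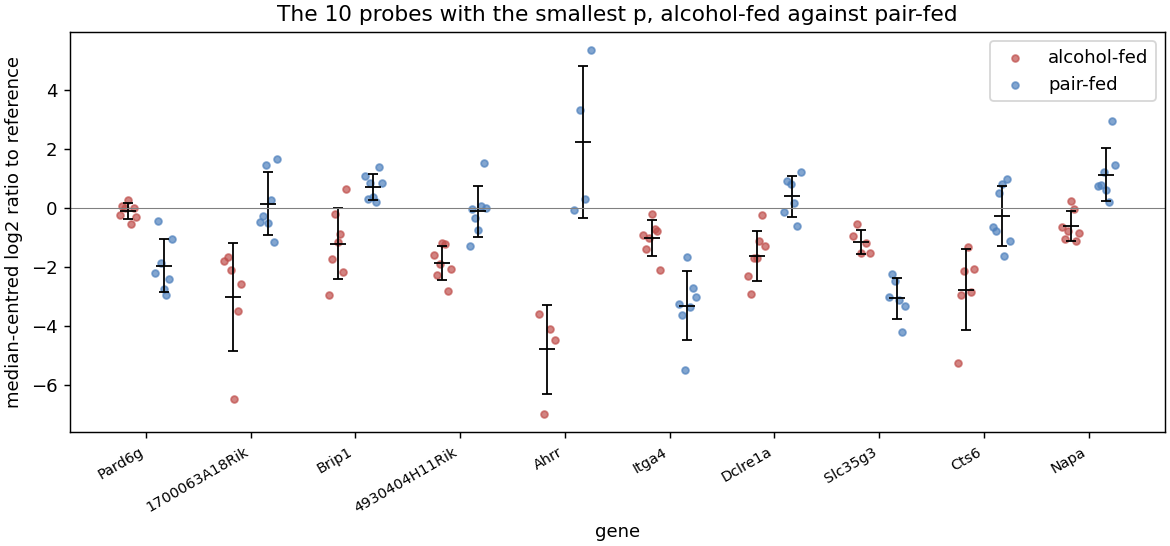
Median-centred log2 ratio to the reference (y axis) of the 10 probes with the smallest p between alcohol-fed and pair-fed (x axis, gene); points are arrays, black bars the group mean and SD. None passed the threshold (adjusted p 0.9996), and Ahrr has the widest gap, -7.02 on the log2 scale from 4 arrays of each group.

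Of 514 measured members of the 32 gene lists, 0 passed between the groups, and 0 passed when adjusted over the list alone. The following are the list members with the smallest p, none of which passed, each with its log2 difference and SE. Among markers of cell types these were, for hepatocytes, the serum glycoprotein gene Ahsg (1.18 ± 0.50), for lung epithelium the phosphate transporter Slc34a2 (-0.998 ± 0.36), for neurons the GABA-synthesising enzyme Gad2 (-0.76 ± 0.40, other probe 0.91) and for glia the intermediate filament Gfap (-1.60 ± 0.53, other probe 0.19). Muscle and blood lists were led by Actn3 of skeletal muscle (-3.31 ± 0.95), the cardiac transcription factor Nkx2-5 (1.44 ± 0.52), the erythroid enzyme Bpgm (-3.32 ± 0.96) and Cd4 of T cells (-1.94 ± 0.62). Epithelial and other organ lists were led by Krt6a of epidermis (-1.52 ± 0.87), Lrp2 of kidney tubules (-1.17 ± 0.68, other probe -0.07), Guca2a of intestine (-0.95 ± 0.53), Pdx1 of pancreas (1.22 ± 0.53) and Psg17 of trophoblast (1.05 ± 0.39). Endothelium was led by Cdh5 (-1.57 ± 0.56), fibrillar matrix by the proteoglycan Dcn (0.75 ± 0.35) and cartilage and bone by Acan, the cartilage proteoglycan (1.14 ± 0.61, other probe 0.61).

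For the response lists the corresponding members were Stra6, the retinol uptake receptor, in ethanol and retinoid metabolism (0.57 ± 0.33), the metallothionein Mt1 in antioxidant defence (1.10 ± 0.54), Dnajb9 in the unfolded protein and amino acid response (-1.07 ± 0.58) and Bag3 in heat shock (0.84 ± 0.42). Metabolic lists gave Pck1 of gluconeogenesis in fasting and glucocorticoid response (-1.49 ± 0.83), Elovl6 in cholesterol and fatty acid synthesis (1.24 ± 0.56), Aldoa in hypoxia and glycolysis (-3.24 ± 0.95) and Ndufs3 in oxidative phosphorylation (-0.86 ± 0.43). Growth lists gave the replication helicase subunit Mcm6 in the cell cycle (1.39 ± 0.50), Bcl2l11 in apoptosis and p53 targets (1.75 ± 0.78), Plagl1 among insulin-like growth factors and imprinted genes (1.13 ± 0.46) and Rpl4 among ribosomal proteins (0.90 ± 0.53). Signalling lists gave Icam1 in interferon and inflammation (1.17 ± 0.55), Egr1 among immediate early genes (-2.21 ± 0.80), Sfrp1 in hedgehog and Wnt signalling (1.30 ± 0.61, other probe 0.25) and Mbd2 in DNA methylation and one-carbon metabolism (1.18 ± 0.41, other probe 0.43). List medians lay between -0.22, for erythroid cells, and 0.38, for hedgehog and Wnt signalling. The lowest adjusted p was 0.925 with camera, 0.970 with an estimated correlation and 0.696 with fry, and 0, 0 and 1 lists had an unadjusted p under 0.05. Median, mean and test differed in sign for glia, epidermis, kidney, intestine, fibrillar matrix, antioxidant defence, apoptosis, insulin-like growth factors, hypoxia, oxidative phosphorylation and immediate early genes. The median 95% confidence half-width of a probe was 1.09 on the log2 scale, and the interval excluded a 2-fold difference for 8.84% of probes and a 4-fold difference for 76.8%.

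Against the reference, which asks how each diet group differed from freely fed controls, the ratios had large values shared by both groups. Positive values are taken as sample over reference; this direction is likely, from the order of the channels in the labels and design text, but not stated, and scale (log2) and array centring are also inferred from the values. If the ratios are reference over sample, every rise and fall named here, lowest and highest included, exchanges, and so does the sign of each difference between the groups. The pool counts as 1 control sample whose own spread is left out of the test, and no array had reversed dyes, so a dye effect is not separated from the difference.

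In the alcohol-fed group Vipr2, a receptor for vasoactive intestinal peptide, was the farthest below the reference (-7.52 ± 0.28, log2 ratio ± SE), followed by the receptor Gpr39 (-6.41 ± 0.33), the RNA-binding protein gene Bicc1 (-6.14 ± 0.38). Next came mitochondrial carbonic anhydrase Car5b (-5.99 ± 0.37), the Wnt ligand Wnt10a (-5.97 ± 0.51) and the kinase Wnk2 (-5.97 ± 0.30). Cdcp3 (-5.92 ± 0.61), the transcription factor Myb (-5.86 ± 0.42), the testis kinase Tssk3 (-5.78 ± 0.42), the kinase Stk24 (-5.77 ± 0.33), the mRNA decapping factor Dcp1a (-5.76 ± 0.34) and Morc4 (-5.70 ± 0.23) fell as well. Farthest above it were Wipf2, an actin regulator (6.60 ± 0.44), Prodh2 of the proline dehydrogenase family (6.35 ± 0.42), Mettl6, a methyltransferase (6.16 ± 0.41). Next came the sensory neuron receptor Mrgprb4 (6.06 ± 0.39), the hair gene Krtap4-13 (6.00 ± 0.40) and Ryr1, the calcium release channel of skeletal muscle (5.91 ± 0.54). Arrdc5 (5.91 ± 0.34), the ubiquitin-conjugating enzyme Ube2r2 (5.87 ± 0.73), plakoglobin gene Jup (5.85 ± 0.46), the translation regulator Paip2 (5.83 ± 0.39), Prom2 (5.75 ± 0.27) and Parp14 (5.72 ± 0.47) rose as well. Each held its direction in 7 of 7 alcohol-fed arrays, with a limma adjusted p of at most 1.53e-05. Other probes of the same gene stood apart for Car5b (-0.57) and for Ryr1, where the other 6 probes lay between -0.05 and 0.94.

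In total limma called 4913 of 20876 probes in the alcohol-fed group, 1675 higher and 3238 lower, in 3688 named genes, and 1484 differed at least 4-fold. The higher share was 34.1%, against 44.2% with values as deposited (1948 higher, 2458 lower) and 48.7% with quantile normalization (2894 and 3047), which moved the median of all probes from 0.01 to 0.14 in both cases. With the ratio turned the main share is 65.9%. Among the 14666 probes with a value on all arrays, 1675 were called higher and 1655 lower, so that the excess of lower calls ended. Leaving out alcohol-fed arrays 2 and 3 and pair-fed array 2, whose deviations correlate most (an alternative chosen after seeing the data), gave 2816 calls, 745 higher and 2071 lower. Without 1 array the higher count fell to 1068 (alcohol-fed 3), 1059 (alcohol-fed 4) and 1114 (alcohol-fed 6).

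Among organ markers in the alcohol-fed group, 0 of 19 hepatocyte markers rose and 5 fell (4 adjusted over the list alone), with Rbp4, the plasma retinol carrier, at -2.40 ± 0.38 and Apoa2 at -1.68 ± 0.33. Of 16 lung epithelium markers 2 rose, 5 fell and 1 had probes called both ways (8 alone), with Slc34a2 at -2.28 ± 0.27 and the transcription factor Nkx2-1 at -3.34 ± 0.43. Of 19 neuronal markers 0 rose and 1 fell (1 alone), Gad2 at -3.32 ± 0.60, whose other probe stood at 0.13, while Dcx stood at 0.80 ± 0.31 and did not pass (adjusted p 0.0647 with limma). Of 16 glial and progenitor markers 1 rose and 4 fell (3 alone), with the water channel Aqp4 at -1.40 ± 0.38 and Sox2 at 1.17 ± 0.34. Of 21 skeletal muscle markers 3 rose and 8 fell (15 alone, 6 of them higher), among them Ryr1 and the myogenic factor Myog at -3.61 ± 0.37. Of 13 heart markers 0 rose and 2 fell (2 alone), Tnnt2 at -4.16 ± 0.82 and Nppa at -1.34 ± 0.36. Of 14 erythroid markers 2 rose and 4 fell (8 alone), with the transferrin receptor Tfrc at -2.99 ± 0.41 and the embryonic globin Hba-x at -3.56 ± 0.56, whose other probes stood at 0.12 and 0.43. Of 15 leukocyte markers 0 rose and 6 fell (6 alone), with Il7r at -3.75 ± 0.37 and Cd4 at -1.96 ± 0.42. Of 14 epidermis markers 0 rose and 2 fell (2 alone), Krt4 at -1.85 ± 0.47 and Krt15 at -1.95 ± 0.55. Of 13 kidney markers 1 rose and 6 fell (8 alone), with Lrp2 at -2.65 ± 0.48, other probe -1.89, and uromodulin gene Umod at -1.23 ± 0.25. Of 12 intestine markers 1 rose and 3 fell (4 alone), with Cldn3 at -2.89 ± 0.26 and Guca2a at -1.79 ± 0.37. Of 11 pancreas markers 2 rose and 4 fell (6 alone), with the elastase Cela1 at -2.94 ± 0.45 and Pdx1 at 1.83 ± 0.38. Of 9 trophoblast markers 3 rose and 1 fell (3 alone), with Psg17 at 1.52 ± 0.28 and Psg23 at 1.41 ± 0.31, whose other probe stood at 0.08. Of 14 endothelial markers 0 rose and 5 fell (4 alone), with Emcn at -1.55 ± 0.35 and Tie1 at -1.23 ± 0.28. Of 16 fibrillar matrix genes 2 rose and 4 fell (5 alone), with Col1a1 at -3.26 ± 0.37 and Col3a1 at 1.54 ± 0.28. Of 16 cartilage and bone genes 1 rose and 6 fell (7 alone), with Col9a1 at -1.88 ± 0.29 and Col9a3 at -1.70 ± 0.31.

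Among response lists in the alcohol-fed group, 2 of 16 ethanol and retinoid genes rose and 4 fell (5 alone, 3 of them higher). The retinoic acid receptor Rara stood at -2.24 ± 0.41, its other 5 probes between -1.29 and 0.28, and catalase gene Cat at -2.69 ± 0.58. Of 15 antioxidant genes 2 rose and 3 fell (5 alone), with thioredoxin gene Txn1 at -3.25 ± 0.69 and the cystine transporter Slc7a11 at -1.91 ± 0.46. Of 17 unfolded protein response genes 1 rose and 0 fell (0 alone), the chaperone Hspa5 at 1.32 ± 0.33 with its other probe at 0.63, beside Hsp90b1 at 0.85 ± 0.33, not past (limma adjusted p 0.0655). Of 10 heat shock genes 1 rose and 1 fell (2 alone), Dnaja1 at 1.14 ± 0.28 and Hspa8 at -3.89 ± 0.40, whose other probe stood at 0.65. Of 15 fasting and glucocorticoid genes 0 rose and 6 fell (6 alone), with the coactivator Ppargc1a at -3.57 ± 0.46 and Pck1 at -2.86 ± 0.56. Of 20 cholesterol and fatty acid genes 1 rose and 1 fell (2 alone), Mvd at 1.63 ± 0.35 and lanosterol synthase Lss at -5.58 ± 0.27. Of 23 cell cycle genes 3 rose and 1 fell (4 alone), with Mcm2 at 1.46 ± 0.34 and Cdc20 at -3.44 ± 0.59. Of 17 apoptosis and p53 genes 0 rose and 2 fell (2 alone), Casp8 at -2.02 ± 0.31 and Fas at -2.47 ± 0.41. Of 23 insulin-like growth factor and imprinted genes 1 rose and 8 fell (13 alone), with Igf1 at -2.49 ± 0.36 and H19 at -2.89 ± 0.47. Of 14 hypoxia and glycolysis genes 0 rose and 6 fell (9 alone), with Pgk1 at -2.75 ± 0.56 and Ldha at -3.46 ± 0.75. Of 19 oxidative phosphorylation genes 1 rose and 4 fell (5 alone), with the cytochrome oxidase subunits Cox7a2 at -2.94 ± 0.34 and Cox4i1 at -2.95 ± 0.58. Of 25 ribosomal protein genes 0 rose and 1 fell (1 alone), Rps16 at -2.90 ± 0.66 with its other probe at -0.53. Rpl11 at -1.03 ± 0.38 did not pass (limma adjusted p 0.0586). Of 19 interferon and inflammation genes 1 rose and 5 fell (11 alone, 5 of them higher), with Tlr4 at -2.14 ± 0.36 and Il1b at -1.71 ± 0.38. Of 13 immediate early genes 2 rose and 1 fell (3 alone), with Egr2 at 4.97 ± 0.38 and Egr1 at -3.15 ± 0.59. Of 18 hedgehog and Wnt genes 2 rose, 3 fell and 1 had probes called both ways (5 alone), with the Wnt receptor Fzd1 at 4.82 ± 0.29 and the hedgehog receptor Ptch1 at -2.71 ± 0.31, whose other probe stood at 0.56. Of 12 DNA methylation and one-carbon genes 0 rose and 2 fell (1 alone), Shmt1 at -1.65 ± 0.38 and Mbd2 at -1.80 ± 0.56, whose other probe stood at 0.77.

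No list passed the test against other genes in the alcohol-fed group. Camera called 0 of 32 (3 with an unadjusted p under 0.05), with a lowest adjusted p of 0.215, or adjusted p = 0.442 with an estimated correlation. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 21, 18 downward and 3 upward. Over all genes tested the mean log2 ratio was -0.199 and the median 0.014, so this downward split need not be particular to these lists. Median, mean and test differed in sign for lung epithelium, epidermis, intestine, trophoblast, ethanol and retinoid metabolism, antioxidant defence, heat shock, fasting and cell cycle. Calls that ended without 1 alcohol-fed array were Mbd2 (without 2, 3, 4, 5 or 7, adjusted p up to 0.0888), Sox2 (without 4, 5 or 7, up to 0.0647), Krt15 (without 6 or 7, up to 0.0545), Aqp4 (without 7, 0.0537) and Nppa (without 5, 0.0532), all by limma. Krt15 also lost its call without the arrays with most placeholders (0.0576). Rpl11 gained a call without alcohol-fed 2 or pair-fed 6 or 7, with array weights or without the arrays with most placeholders (0.0360 to 0.0488). Hsp90b1 gained one without alcohol-fed 6 or the arrays with most placeholders, with array weights, robust eBayes, values as deposited, quantile or scale normalization (0.0263 to 0.0479). Dcx gained one with values as deposited, quantile normalization or robust eBayes (0.0266 to 0.0444). Averaging a gene's probes ended the calls of Hspa5 (0.0579), Rara (0.0759) and Mbd2 (0.163), and values as deposited ended that of Aqp4 (0.0517). Leaving out the 3 correlated arrays ended those of Cat, Hspa5, Mbd2, Mcm2, Nppa, Psg23, Slc7a11 and Sox2 (0.0504 to 0.0894).

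In the pair-fed group Vipr2 was again the lowest (-7.07 ± 0.28), followed by the chemokine Ccl5 (-6.34 ± 0.32), Gpr39 (-6.33 ± 0.33). Next came Wnk2 (-6.31 ± 0.30), Car5b (-6.29 ± 0.37), Bicc1 (-6.28 ± 0.38) and Lss (-6.01 ± 0.27). Socs4, a cytokine signalling suppressor (-5.99 ± 0.50), the glypican Gpc4 (-5.90 ± 0.36), Psat1 of serine synthesis (-5.88 ± 0.58), the keratin Krt13 (-5.87 ± 0.29) and the mitochondrial iron-sulfur protein gene Cisd1 (-5.86 ± 0.27) fell as well. The largest rises were those of Hspg2, the basement membrane proteoglycan perlecan (6.48 ± 0.30), Sertad3 (6.26 ± 0.29), Arrdc5 (6.15 ± 0.34), Mrgprb4 (6.07 ± 0.39), Prom2 (5.88 ± 0.27) and Ttc14 (5.82 ± 0.33). Naif1 (5.68 ± 0.34), Mettl6 (5.66 ± 0.41), Paip2 (5.65 ± 0.39), the cadherin Cdh9 (5.65 ± 0.31), Ppp1r17 (5.60 ± 0.51) and Ube2r2 (5.55 ± 0.73) rose as well. The limma adjusted p was at most 3.35e-05, and each held its direction in 7 of 7 pair-fed arrays except Ube2r2, with 6 of 7. Other probes stood at -1.16 for Car5b, 1.23 for Gpc4 and -0.42 for Ttc14.

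In total limma called 4450 of 20876 probes in the pair-fed group, 1641 higher and 2809 lower, in 3359 named genes, and 1286 differed at least 4-fold. The higher share was 36.9%, against 47.5% as deposited (1855 higher, 2053 lower) and 48.4% with quantile normalization (2321 and 2476), where the median of all probes moved from -0.03 to 0.09 and 0.08. With the ratio turned the main share is 63.1%. Among probes with a value on all arrays, 1776 were called higher and 1696 lower. The higher count was 1091 without pair-fed 4, 1045 without pair-fed 5 and 1021 without the 3 correlated arrays, where 2168 were lower.

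Among organ markers in the pair-fed group, 6 of 19 hepatocyte markers fell and 0 rose (6 alone), with Rbp4 at -2.63 ± 0.38. Of 16 lung epithelium markers 5 fell, 0 rose and 1 had probes called both ways (7 alone), the lipid transporter Abca3 at 4.70 ± 0.62 with its other probe at -2.18. Of 19 neuronal markers 2 rose, 0 fell and 1 was called both ways (7 alone), Gad2 at -4.23 ± 0.64 with its other probe at 0.89. Of 16 glial markers 1 rose and 1 fell (4 alone), with Sox10 at -1.47 ± 0.43. Of 21 skeletal muscle markers 3 rose, 7 fell and 1 was called both ways (12 alone), with Myog at -3.60 ± 0.37. Of 13 heart markers 0 rose and 4 fell (5 alone), with Tnni3 at -1.13 ± 0.29. Of 14 erythroid markers 1 rose, 4 fell and 1 was called both ways (6 alone), with the embryonic globin Hbb-bh1 at -4.38 ± 0.75. Of 15 leukocyte markers 0 rose and 5 fell (5 alone), with Il7r at -3.25 ± 0.37. Of 14 epidermis markers 0 rose and 1 fell (0 alone), Krt15 at -1.70 ± 0.55. Of 13 kidney markers 0 rose and 5 fell (5 alone), with Lrp2 at -1.82 ± 0.38 and its other probe at -1.48. Of 12 intestine markers 0 rose and 1 fell (1 alone), Cldn3 at -2.71 ± 0.26. Of 11 pancreas markers 2 rose and 4 fell (6 alone), with Iapp at -1.54 ± 0.29. Of 9 trophoblast markers 1 rose and 1 fell (2 alone), with Plac1 at -1.49 ± 0.32. Of 14 endothelial markers 0 rose and 3 fell (3 alone), with Esam at -2.16 ± 0.37. Of 16 fibrillar matrix genes 1 rose and 2 fell (5 alone), with Col1a1 at -2.71 ± 0.37. Of 16 cartilage and bone genes 1 rose and 7 fell (9 alone), with osteocalcin gene Bglap at 1.13 ± 0.25.

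Among response lists in the pair-fed group, 1 of 16 ethanol and retinoid genes rose and 5 fell (4 alone), with Cat at -3.00 ± 0.58. Of 15 antioxidant genes 0 rose and 0 fell (0 alone), with Txn1 at -2.43 ± 0.85 and a limma adjusted p of 0.0549, which came to 0.0463 without alcohol-fed 3 and 0.0286 without alcohol-fed 7. Of 17 unfolded protein response genes 2 rose and 0 fell (1 alone), with Hspa5 at 1.37 ± 0.33 and its other probe at -0.47. Of 10 heat shock genes 1 rose and 1 fell (2 alone), with Hspa8 at -3.64 ± 0.40 and its other probe at 0.42. Of 15 fasting genes 1 rose, 4 fell and 1 was called both ways (5 alone), with Ppargc1a at -2.71 ± 0.46. Of 20 cholesterol and fatty acid genes 2 rose and 1 fell (3 alone), the latter Lss. Of 23 cell cycle genes 1 rose and 6 fell (7 alone), with Mcm4 at -2.33 ± 0.51. Of 17 apoptosis genes 0 rose and 2 fell (2 alone), with Casp8 at -1.73 ± 0.31. Of 23 insulin-like growth factor and imprinted genes 2 rose and 9 fell (12 alone), with Igf1 at -2.39 ± 0.36. Of 14 hypoxia and glycolysis genes 0 rose and 1 fell (0 alone), the peptide hormone gene Adm at -1.19 ± 0.40. Of 19 oxidative phosphorylation genes 2 rose and 2 fell (7 alone), with Cox7a2 at -2.40 ± 0.37. Of 25 ribosomal protein genes 1 rose and 1 fell (2 alone), with Rps16 at -4.07 ± 0.66 and its other probe at -0.89. Of 19 interferon and inflammation genes 1 rose and 4 fell (6 alone), with Il1b at -2.05 ± 0.38. Of 13 immediate early genes 1 rose and 0 fell (1 alone), Egr2 at 5.17 ± 0.38. Of 18 hedgehog and Wnt genes 3 rose, 4 fell and 1 was called both ways (7 alone), with Fzd1 at 4.76 ± 0.29. Of 12 DNA methylation genes 0 rose and 2 fell (2 alone), with Mbd2 at -2.23 ± 0.61 and its other probe at -0.40.

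Camera called 0 of 32 lists in the pair-fed group (5 with an unadjusted p under 0.05), with a lowest adjusted p of 0.259, or adjusted p = 0.581 with an estimated correlation. Fry called 20, 18 downward and 2 upward, where all genes tested had a mean log2 ratio of -0.195 and a median of -0.031. Median, mean and test differed in sign for epidermis, ethanol and retinoid metabolism, antioxidant defence and hedgehog and Wnt signalling. By limma, the call of Adm ended without alcohol-fed 3 or any of pair-fed 1 to 6 (adjusted p 0.0509 to 0.135), that of Krt15 without pair-fed 1, 3, 4, 5, 6 or 7 (up to 0.0748), that of Sox10 without pair-fed 1 or 6 (0.0741 and 0.0675) and that of Mbd2 without pair-fed 2 or 6 (0.0595 and 0.0531). Values as deposited ended the calls of Adm, Krt15, Sox10 and Tnni3 (0.0576 to 0.0834). Quantile normalization ended those of Adm and Krt15 (0.0628 and 0.0544), robust eBayes that of Adm (0.0529) and array weights that of Krt15 (0.0575). Leaving out the arrays with most placeholders ended those of Krt15 and Sox10 (0.0718 and 0.137), leaving out the correlated arrays those of Adm and Mbd2 (0.105 and 0.0838), and averaging its probes that of Hspa5 (0.246).

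Vipr2, Gpr39, Wnk2, Car5b, Bicc1, Mrgprb4, Arrdc5, Prom2, Mettl6, Paip2 and Ube2r2 were among the largest changes of both groups. Of the probes called against the reference, 781 were higher and 1937 lower in both groups, 0 went in opposite directions, 2195 were called only in the alcohol-fed and 1732 only in the pair-fed group, while independent lists of these sizes would share 131.7 and 435.7. The split of the shared calls changed with the setting, to 969 higher and 1391 lower with values as deposited and 1379 and 1732 with quantile normalization. It was 1073 and 1663 with robust eBayes and 852 and 1144 among probes with a value on all arrays. Leaving out the 3 correlated arrays gave 1634 shared calls, 359 higher and 1275 lower. Across probes, which are not independent replicates, the mean ratios of both groups correlated at r = 0.832 with a covariance of 1.02. Simulated unchanged groups gave r = 0.00123, a covariance of 0.000261 and 0 shared calls when the reference did not deviate. They gave r = 0.471, a covariance of 0.187 and 5.4 shared calls when it deviated like a pool of 7 samples, and they gave r = 0.867, a covariance of 1.34 and 5284 shared calls when it deviated like 1 sample. With the deviation of a pool of 7 the unchanged groups had 61.2 and 46.8 calls, fewer than the 4913 and 4450 observed. With that of 1 sample they had 7532 and 7387, more than observed. The observed minus the simulated covariance was 0.828 for a pool and -0.328 for 1 sample. The reference is 1 pool and cannot be split, so part or all of the calls and of their overlap may come from it.

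**Figure D3:**
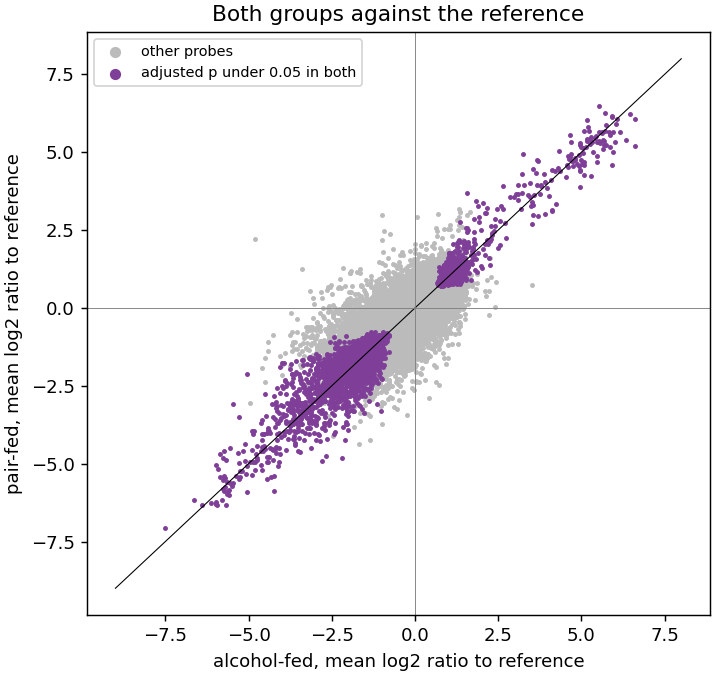
Mean log2 ratio to the reference of each probe in the pair-fed group (y axis) against the alcohol-fed group (x axis); purple points passed adjusted p under 0.05 in both, grey points did not, and the line marks equal values. The 781 shared higher and 1937 shared lower probes, 1379 and 1732 with quantile normalization, lie along the line in this plot of median-centred values (r = 0.832 across probes).

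A limit on every gene named here is that probes of 1 gene seldom shared their ratio. Over 866 genes with 2 probes each, the ratios of the probes correlated across genes at r = 0.035 in the alcohol-fed group (95% interval -0.0317 to 0.101, permutation p 0.304) and at r = 0.0467 in the pair-fed group (-0.0200 to 0.113, permutation p 0.171). Where both probes were called, 27 of 50 genes had them in one direction in the alcohol-fed group (54.0%, exact interval 39.3% to 68.2%) and 24 of 45 in the pair-fed group (53.3%, 37.9% to 68.3%).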

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

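The tests of explanations in this part, the comparison of splits included, were chosen after the results were seen. In 21 of 218 gene groups of 1 probe and 1 diet group (9.63%), and in 1 of 8 array measures, 1 array lay farther from its neighbour than Dixon's 95% value for a gap allows; chance does so in about 1 of 20 groups. The values, median-centred log2 ratios, were the following. In the alcohol-fed group array 1 stood at -4.16 for Aldoa (next -2.33) and -8.00 for Car5b (next -6.31), array 2 at -0.71 for Gad2 (next 0.002) and -10.29 for Tnnt2 (next -3.72), and array 3 at 4.61 for Mettl6 (next 5.95) and -6.57 for Pgk1 (next -2.77). Array 4 stood at 2.23 for Dnajb9 (next -0.20) and -3.66 for Emcn (next -1.73), and array 5 at -1.51 for Slc34a2 (next -2.35). Array 6 stood at -4.58 for Rbp4 (next -2.68) and -4.78 for Rara (next -2.29), and array 7 at -1.06 for Mt1 (next 0.68) and -5.09 for Krt4 (next -1.88). In the pair-fed group array 1 stood at -6.00 for Ppargc1a (next -2.86), and array 2 at 1.93 for Mcm6 (next 0.18), -2.69 for Socs4 (next -5.81), 2.07 for Ppp1r17 (next 5.37), -0.66 for Ube2r2 (next 4.66) and -1.02 for a second Gad2 probe (next -4.29). Array 6 stood at -3.40 for Acan (next -0.55) and -0.40 for Iapp (next -1.40). Alcohol-fed array 6 had 1708 placeholders, where the next of its group had 980.

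No probe passed limma's test between alcohol-fed and pair-fed (881 at an unadjusted p under 0.05, and 0 lists by camera and fry). Of 100 splits of the 14 arrays drawn from 1716 possible, the real one included, 100 gave at least the real 0 probes, with 2 as the highest of the others, and 100 at least the real 0 lists, with 3 as the highest, which with a real count of 0 holds by construction and says nothing about chance. Of the same splits 63 had at least the real 881 probes at an unadjusted p under 0.05. The split with most probes at an unadjusted p under 0.05 had 2253, against a median of 941, and held on 1 side alcohol-fed 2 and 3 and pair-fed 2, the arrays whose deviations correlate most (0.184 to 0.271 across probes). The 20 splits with these 3 arrays on 1 side had a median of 1257 such probes, against 886.5 for the other 80. Of the 10 splits with most such probes, 9 had the 3 on 1 side. The 3 arrays were picked from these data for that correlation, which can itself raise such counts, so these split counts are no separate support. By that correlation these 3 arrays may not be independent of each other. They also had the highest deposited medians (0.55, 0.57 and 0.63) and the most values within 0.012 above 0 (219, 254 and 183). A spread too large for small differences is a candidate explanation: 0% of simulated 2-fold differences were called, so a difference of that size between the diets stays open.

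Both groups shared large ratios against the reference. A difference in the named transcripts as the whole cause is argued against, since only 54% of genes with both probes called had them in one direction. Whether a link to how bright a spot is contributes stays open, since brightness was not measured. Olfactory receptors, genes few fetal cells are known to use, had 136 probes with a median log2 ratio of -0.75. That of 15941 other named probes was 0.01, a difference of -0.76 over the means of all 14 arrays. The difference was -0.73 in the alcohol-fed and -0.64 in the pair-fed group (permutation p 1e-04 for each, the smallest that 10000 permutations can give). The permutation treats probes as independent, which they may not be, and the kinds of probe were not matched. A lower ratio of this family is therefore not a measure of brightness. Whether the feeding regimens differ from ad libitum feeding here cannot be told apart from dye effects, because 0 arrays carried the sample in Cy3, and a deviation of the reference pool itself stays open too.

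Probes of 1 gene seldom shared their ratio. Probe names out of step with the values are argued against: 25 ribosomal protein probes had at least 5 values just above 0 at their own place in the table, against at most 9 at 40 shifted places. Random error independent between arrays is argued against by r = 0.832 between the groups' mean ratios across probes, where simulated arrays with such error alone gave r = 0.00123. Error of the shared reference, which gave r = 0.471 to 0.867 in simulation, is not excluded. Cross-hybridisation and spot effects were not tested and stay open, and no biological explanation was tested.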

How the results depend on the processing

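The count of 0 probes between alcohol-fed and pair-fed held under every alternative run. By limma, 561 (among probes with a value on all arrays) to 1123 (without pair-fed 2) had an unadjusted p under 0.05. The lowest adjusted p lay between 0.141 (without alcohol-fed 1) and 1. With the replicate number as a block, limma called 0 probes (1032 unadjusted, lowest adjusted p 0.729) and camera 0 lists (0.903). The labels do not say whether the numbers pair the samples, and weak correlations cannot exclude it. Deviations of same-numbered arrays correlated at -0.0775 to 0.184, 1 of 7 over 0.1. Within the other group, 4 of 14 arrays correlated best with the array of their own number. Leaving out each array in turn gave 0 to 0 probes for alcohol-fed against pair-fed, 3590 (without alcohol-fed 4) to 5297 (without pair-fed 6) for alcohol-fed against the reference, 3256 (without pair-fed 5) to 4891 (without alcohol-fed 6) for pair-fed, and 2125 to 2798 shared. Total counts moved by over 1.5 times when alcohol-fed 2 and 3 and pair-fed 2 were left out, an alternative chosen after seeing the data (2816 probes for alcohol-fed and 1634 shared, from fewer arrays), and with fry, which does not compare a list with other genes (21 lists for alcohol-fed and 20 for pair-fed, where camera called 0). Counts in 1 direction against the reference moved by over 1.5 times under more settings. The 1675 higher probes of the alcohol-fed group became 2894 with quantile normalization, 745 without the correlated arrays, and 1068, 1059 and 1114 without alcohol-fed 3, 4 or 6, and its 3238 lower ones 1655 among probes with a value on all arrays and 2071 without the correlated arrays. The 1641 higher probes of the pair-fed group became 1021 without the correlated arrays and 1091 and 1045 without pair-fed 4 or 5, and its 2809 lower ones 1696 among probes with a value on all arrays. The 781 shared higher probes became 1379 with quantile normalization and 359 without the correlated arrays, and the 1937 shared lower ones 1144 and 1275 with a value on all arrays and without the correlated arrays. For the named genes 0 values that passed reversed: between the groups 1081 values kept their direction and side of the threshold and 1 turned, against the reference 2183 kept both, 25 lost and 15 gained a call for alcohol-fed, and 1378 kept both, 30 lost and 2 gained one for pair-fed. Leaving out the dimmest probes was planned and not run, as no signal over background was used here, so what dim spots limit is unknown.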

Other observations

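The test in this part was chosen after its pattern was seen. Values just above 0 recur in certain probes. Of 76 ribosomal protein probes, genes known to be among the most highly expressed, 25 had at least 5 such values, against 92 of all 16635 named probes (odds ratio 120, 95% interval 67.2 to 211, Fisher's exact test p 6.65e-39). Spots at the top of the scale in both channels are a candidate explanation, as their ratio would stay close to 0 whatever the levels. The small ratios of ribosomal protein genes may then understate a difference.

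Shares of called probes by the kind of sequence behind them were also computed. In the alcohol-fed group 20.4% of 7775 probes from cDNA clones were called, 55.6% of them lower, against 25.8% of 6532 RefSeq probes, 70.5% of them lower. In the pair-fed group the shares were 19.1%, 47.1% lower, and 23.5%, 70.9% lower. With the ratio turned, each share given as lower is the share of higher calls. No test was run on these shares. The correlation between probes of 1 gene was also computed within kinds of probe, subsets chosen after the values were seen. Across 306 genes without cDNA clone probes r was 0.0672 for alcohol-fed and 0.0803 for pair-fed against the reference. Across 24 genes with RefSeq probes only it was 0.238 (95% interval -0.183 to 0.585) and 0.230 (-0.192 to 0.579). With the mean of all arrays r was 0.0876 (-0.0248 to 0.198) without cDNA clone probes and 0.34 (-0.0741 to 0.653) with RefSeq probes only. The adjusted permutation p was 0.281 for each, over the 6 such correlations.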
